A study of Sus scrofa with 23 samples.

How the data were processed

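The study measured messenger RNA in articular cartilage of pigs with the Affymetrix Porcine Genome Array, a short-oligonucleotide array on which each transcript is read by 1 or more probe sets. The samples came from affected and non-affected sib-pairs of a Duroc and Pietrain cross, and from 2 joint surfaces, the medial part of the humeral condyle and the medial femoral condyle. According to the labels, total RNA was extracted with TRI Reagent and labelled with biotin before hybridisation. The labels give 23 arrays: 8 of affected and 6 of non-affected humerus, and 4 of affected and 5 of non-affected femur. The labels do not say that arrays of a group came from separate animals, and they do not say which animals were sibs, so the p-values measure only the spread between these samples.

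The deposited table holds 1 value per probe set and array on a log2 scale. The submitters' processing notes name GCOS 1.1.1 for the image analysis. The step that normalised the arrays is not given in the sources used here. The table has 24123 probe sets, of which 124 are controls. Its values run from 4.00 to 17.6, with a floor at 4 on the log2 scale, or 16 on a linear scale, and the array medians run from 6.04 to 6.32. They were used as deposited. The platform annotation gave 1 gene symbol for 10099 probe sets and several for 198, and 13826 probe sets are not in it; gene names were taken only from that annotation. Image files were not used here.

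Pairs of arrays of the same group were compared before any test. The values of humerus affected 5 and 6 differed by a standard deviation of 0.108 over the probe sets (r = 0.998), and those of femur non-affected 1 and 2 by 0.214 (r = 0.994). The next closest pair differed by 0.341, and the median over other pairs of 1 group was 0.517. Both close pairs fell under a bound of 0.25 and were averaged as 1 sample each, because they could hold the same RNA. This left 21 samples: 7 affected and 6 non-affected in the humerus, and 4 affected and 4 non-affected in the femur. The labels do not say whether the pairs are repeat hybridisations.

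Control probe sets were left out, and then the 7200 probe sets with a mean under the 30th percentile (5.30), which left 16799 for the tests. Of these, 8071 carry 1 gene symbol, for 5905 genes. limma 3.58.1 in R 4.3.3 fitted linear models with moderated variances (lmFit, eBayes). Affected against non-affected was tested over both sites with site in the model. It was then tested within the humerus and within the femur in a fit of the 4 group means, where the difference between both within-site effects (the interaction) was tested as well. Femur against humerus was tested with status in the model. Differences are affected minus non-affected, or femur minus humerus, on the log2 scale. P-values were adjusted by the method of Benjamini and Hochberg within each comparison, and a call is an adjusted p under 0.05.

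Lists of genes for cartilage processes and for cells other than chondrocytes were tested with limma's camera at its preset correlation of 0.01, for lists with at least 5 measured members, using the brightest probe set of each gene. Adjustment was over the 26 lists tested in a comparison. Camera with an estimated correlation and fry were run beside it. For each list the count of called members is given over all genes tested and adjusted over the list alone. Genes named in the text follow a fixed rule: probe sets with exactly 1 symbol, the probe set with the smallest p in the comparison, the 12 largest changes per direction for the site comparison and the comparison over both sites, 5 per direction within each site, the 5 smallest p for the interaction, and 3 members per list for the site comparison and the comparison over both sites. Where fewer than 5 passed in a direction, the smallest p-values filled up to 5, which are given as values only. List members named outside that rule were chosen after their values were seen. Comparisons, lists, rule, filter and the alternatives other than those of the next sentence were chosen before the data were examined. Treating the close pairs as 1 sample each, and adding the bone, myeloid and muscle list scores as covariates, was decided after the data were seen.

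The steps were tested on simulated data with known changes, and the recovered shares are given beside each comparison. Simulated values were drawn independently for each gene, with no floor and no group differences other than the planted ones. The recovered shares therefore check the steps and do not give the power in the real data. Single list scores were compared by two-sided exact permutation tests in scipy 1.17.1 (numpy 2.4.6, Python 3.11.15), and correlations over 13 samples by permutation. Plots were drawn with matplotlib 3.10.9. Alternatives covered the filter, the scaling of arrays, the floor, the variance model, array weights, probe sets per gene, the samples in each fit, the set test, covariates, and leaving out each array. The list tests were not rerun without single arrays. The number of arrays limits the precision of every value. A sib-pair term was left out because pairs are not labelled.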

Results

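Osteochondrosis is a disorder of growing joint cartilage in which cartilage fails to turn into bone in an orderly way. Transcript levels were measured in articular cartilage of affected and non-affected pigs at 2 sites, the medial humeral condyle of the elbow and the medial femoral condyle of the knee. The 21 samples comprised 7 affected and 6 non-affected humeral samples and 4 affected and 4 non-affected femoral samples. Array medians were 6.10 ± 0.04 (SD, n = 9) in the femur and 6.27 ± 0.04 (SD, n = 14) in the humerus, in log2 units. On average 4.55% of the probe sets of a femoral array and 2.12% of those of a humeral array lay at the floor. The first principal component held 43.5% of the variance and the second 16.3%. All 8 femoral samples lay between 26.9 and 58.4 on the first component, and 12 of the 13 humeral samples between -53.2 and -0.80. The exception was humerus non-affected 5, at 29.0.

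**Figure D1:**
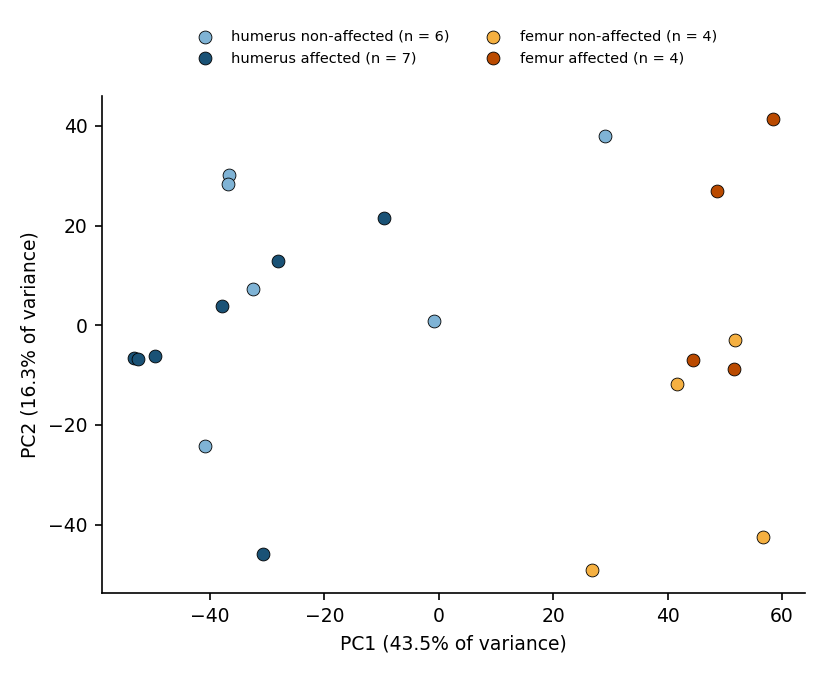
Each point is 1 of 21 samples, placed by its score on the first principal component (horizontal, 43.5% of the variance) and the second (vertical, 16.3%), coloured by site and status. The 8 femoral samples lie between 26.9 and 58.4 on the first component, and humerus non-affected 5 lies among them at 29.0.

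The first question was which transcripts mark affected cartilage whatever the joint. Across both sites no probe set passed the adjusted threshold. The gene with the largest difference among those with the smallest p-values was ANGPTL4, a secreted inhibitor of lipoprotein lipase that responds to low oxygen and to fatty acids. It averaged 10.18 in affected and 8.78 in non-affected femur, and 10.09 against 9.02 in the humerus. Genes of neutrophil granules, of bone matrix and of the cell cycle leaned to the affected side as lists, and all 10 measured genes of cholesterol and lipid synthesis leaned to the other. The femur did not share the lean of the cholesterol genes, since 9 of 10 leaned higher in affected femur. The neutrophil lean lay mostly in the humerus, where the list mean differed by 1.86, against 0.12 in the femur. That of the cell cycle lay mostly in the femur, at 0.30 against 0.01 in the humerus.

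ANGPTL4 lay 1.20 ± 0.27 (SE) higher in affected cartilage with an adjusted p of 0.398, and 10 of 11 affected samples lay above the non-affected mean. Its second probe set gave 1.02. On the same side, TNFAIP8, a regulator of cell death, differed by 0.35, the reductase-like AKR1CL1 by 0.41, LOC100519177 by 0.38 and LOC100520452 by 0.21. On the other side, the cargo receptor TMED10 differed by -0.43 (adjusted p = 0.355) and EXOSC7, a part of the RNA exosome, by -0.54. TUSC2, a mitochondrial protein, differed by -0.42, the nucleoside transporter SLC29A1 by -0.32 and POGLUT1, which glycosylates Notch receptors, by -0.41. limma called 0 of 16799 probe sets, with 1223 at an unadjusted p under 0.05 where 839.95 would fall by chance, and the smallest adjusted p was 0.355. The equal-weight mean of both within-site differences called 22 instead, 4 higher and 18 lower, TMED10 among them. In simulated data this comparison recovered 53.7% of changes of 0.5 and 92.5% of changes of 1 log2 unit, over 16799 genes. Genes were independent there, so these shares do not show that changes of such sizes are absent here.

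Neutrophil genes had a median difference of 1.20, with 6 of 6 positive, and camera's preset called them (adjusted p = 0.00276; adjusted p = 0.733 with an estimated correlation). Among them S100A8, a calcium-binding protein of granulocytes, differed by 1.11, S100A12 by 0.93 (3 of 8 femoral samples at the floor) and the antimicrobial peptide PR39 by 2.53, with 4 of 13 humeral samples at the floor. Cell cycle genes, with a median of 0.13 and 15 of 17 positive, were called as well (adjusted p = 0.0148; adjusted p = 0.822 with an estimated correlation), and MCM5 of the replication helicase differed by 0.34. The bone matrix genes had a median of 0.17, with 6 of 6 positive (adjusted p = 0.0317; adjusted p = 0.211 with an estimated correlation). Bone sialoprotein, IBSP, differed by 1.48 and osteocalcin, BGLAP, by 1.12, while the osteoblast factor SP7 had probe sets of both signs, -0.37 and 0.23. With the bone list as a covariate the neutrophil and cell cycle lists were not called; the bone list itself cannot be judged by it. The bone list also lost its call without the filter (adjusted p = 0.0774) and with probe sets averaged per gene (adjusted p = 0.153). Cholesterol genes had a median of -0.33 (adjusted p = 0.0541), with -0.75 in the humerus and 0.36 in the femur. Neutrophil genes had 1.89 in the humerus and 0.18 in the femur, cell cycle genes 0.01 and 0.26, and bone matrix genes 0.24 and 0.22. Adjusted over the list alone, 1 gene of all lists passed, the growth factor TGFB3 at -0.46 (adjusted p = 0.0402), against 0 over all genes.

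Within the humerus the question was which transcripts mark affected elbow cartilage. No probe set was called there either. The gene with the largest difference among those with the smallest p-values was TNFRSF12A, the receptor of the cytokine TWEAK, which is induced by growth factors and injury. It averaged 8.42 in affected and 9.56 in non-affected samples. As lists, genes of cholesterol synthesis, hypoxia and cartilage matrix leaned lower in affected cartilage, and genes of neutrophils, macrophages, osteoclasts, the interferon response and oxidative phosphorylation leaned higher.

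The difference of TNFRSF12A was -1.14 (adjusted p = 0.641), and all 7 affected samples lay under the non-affected mean. TMED10 differed by -0.44, with all 7 affected samples below every non-affected sample, and EXOSC7 by -0.55. PLP2, a protein of the endoplasmic reticulum, differed by -0.64 and the cell cycle regulator CDK2AP1 by -0.45. On the higher side were the glucose transporter SLC5A1 at 0.52, ZC3H4, which restrains transcription outside genes, at 0.37, IFN-DELTA-1 at 0.45, the sodium-proton exchanger SLC9A5 at 0.34 and TAP1, which loads peptides for antigen presentation, at 0.54. limma called 0 of 16799 probe sets, with 1100 at an unadjusted p under 0.05, and the smallest adjusted p was 0.641. Simulated changes of 1 log2 unit were recovered in 82.7% of cases and those of 0.5 in 27.8%, over 16799 genes.

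Camera's preset called 11 lists in the humerus, none of which passed with an estimated correlation or by fry, and no member of any list was called over all genes or adjusted over the list alone. The cholesterol genes had a median of -0.75, with 10 of 10 negative (adjusted p = 9.84e-07; adjusted p = 0.314 with an estimated correlation). Among them the sterol enzymes SQLE and CYP51 differed by -0.94 and -0.93, and FDFT1 by -0.67. The 25 oxidative phosphorylation genes had a median of 0.13, with 23 positive (adjusted p = 2.00e-05; adjusted p = 0.314 with an estimated correlation). Neutrophil genes had a median of 1.89, interferon response genes 0.39 and osteoclast genes 1.05, with preset adjusted p of 8.27e-04, 0.00110 and 0.00716 (each adjusted p = 0.314 with an estimated correlation). Genes of hypoxia had a median of -0.20 (adjusted p = 0.00343; adjusted p = 0.369 with an estimated correlation), those of the unfolded protein response -0.18 (adjusted p = 0.00716; adjusted p = 0.369 with an estimated correlation) and myeloid genes 0.83 (adjusted p = 0.00503; adjusted p = 0.369 with an estimated correlation). Matrix proteases had a median of 0.47 (adjusted p = 0.0172; adjusted p = 0.369 with an estimated correlation). Cartilage matrix genes had a median of -0.16, with 10 of 11 negative, COL2A1 at -0.62 and CILP at -1.18 (adjusted p = 0.00503; adjusted p = 0.314 with an estimated correlation). TGF-beta and BMP signalling had a median of -0.19 (adjusted p = 0.0283; adjusted p = 0.314 with an estimated correlation). With the myeloid list as a covariate the interferon genes had a median of -0.03 (adjusted p = 0.167). The matrix proteases then had 0.05 (adjusted p = 0.453). The hypoxia and TGF-beta lists were not called either, but kept medians of -0.15 (adjusted p = 0.166) and -0.12 (adjusted p = 0.0643). The myeloid list itself cannot be judged by this covariate. With the bone list as a covariate the protease, hypoxia, unfolded protein response, TGF-beta and myeloid lists were not called, and with probe sets averaged per gene the cartilage list was not (adjusted p = 0.0622). Tested as 1 mean per sample, the cholesterol list differed by -0.72 (two-sided exact permutation p = 0.0163), which did not pass adjustment over 56 such tests. Humerus non-affected 5 stood above the rest of its group for the hypoxia list (11.37, next 10.62) and the unfolded protein response list (10.36, next 10.04). How far the differences of both lists rest on that sample was not tested.

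In the femur, where the question was the same for the knee, limma called probe sets between affected and non-affected cartilage, but chance is not excluded for their number and none of the named genes was called with the femoral arrays fitted alone. FAU, a ribosomal protein made as a fusion with a ubiquitin-like domain, CES1, an esterase of liver and macrophages, FAM46C, which lengthens poly(A) tails, and IGFBP6, a secreted binder of insulin-like growth factor, were all lower in affected samples. KNG1, the precursor of kinins, and NUP50 of the nuclear pore were higher. For FAU, CES1 and FAM46C the 4 non-affected femoral samples stood above affected femur and above the means of both humeral groups. The macrophage genes and the genes of oxidative phosphorylation leaned lower as lists, and those of the cell cycle, hypoxia and cartilage matrix leaned higher.

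FAU averaged 5.65 ± 0.88 (SD, n = 4) in affected and 8.54 ± 0.42 (SD, n = 4) in non-affected femur, against 5.37 and 5.20 in the humerus. Its difference was -2.89 ± 0.31 (SE, adjusted p = 4.16e-05), but its other probe sets gave -0.11 and -0.23. CES1 changed by -3.04 (adjusted p = 0.00275) and FAM46C by -2.52 (adjusted p = 0.00204), where a second FAM46C probe set gave 0.08. IGFBP6 changed by -2.17 (adjusted p = 0.0156), and its second probe set gave -1.98 (adjusted p = 0.0212). BPIFA2, a secreted protein of the salivary glands, changed by -3.44 (adjusted p = 0.0353), with 2 of 8 femoral samples at the floor. KNG1 rose by 0.88 (adjusted p = 0.00894), with -0.10 at its other probe set, and NUP50 by 0.87 (adjusted p = 0.0137). SREK1IP1, which binds a splicing regulator, rose by 0.87 (adjusted p = 0.0191). RB1CC1, which starts autophagy, rose by 1.04 and EGLN1, the oxygen sensor that marks hypoxia-inducible factor for decay, by 0.92 (both adjusted p = 0.0467). In each of these genes except BPIFA2 (3 of 4) all 4 affected samples lay beyond every non-affected sample. The probe set with the smallest p of all carries no gene name. It read 4.06, near the floor, in non-affected femur and between 6.05 and 6.22 in the other 3 groups.

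**Figure D2:**
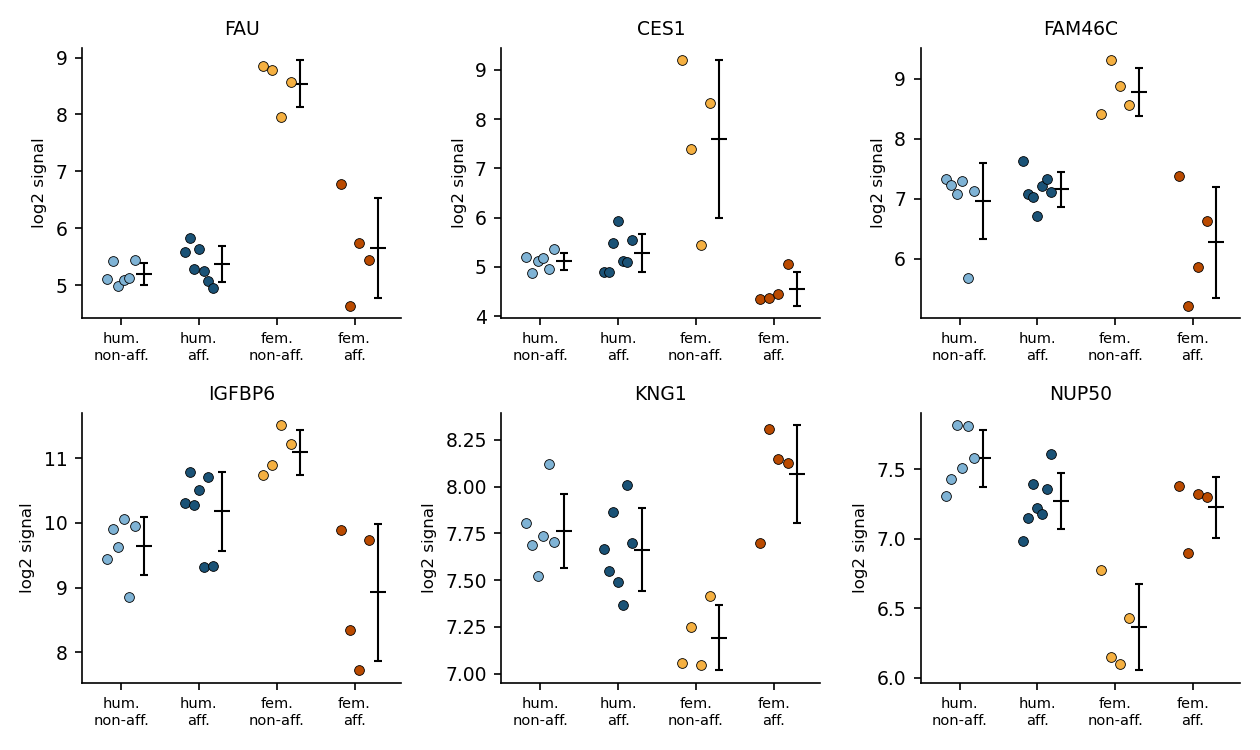
Log2 signal (vertical axis) of 6 genes called in the femur, in each of the 21 samples by group (horizontal axis); the line beside each group is the mean with its SD. For FAU, the non-affected femoral samples average 8.54 and the other 3 groups between 5.20 and 5.65.

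limma called 192 probe sets in the femur, 66 higher and 126 lower, with 3422 at an unadjusted p under 0.05; they include 85 named genes, 12 higher and 73 lower. This count rests on few samples. It was 59 with array weights, 67 with 1 probe set per gene, 600 with 23 arrays, 1577 with the bone list and 87 with the myeloid list as a covariate. It was 450 without femur affected 1, 66 without femur affected 2, 54 without femur affected 3 and 439 without femur affected 4. It was 53 without femur non-affected 3, 82 without femur non-affected 4 and 293 without femur non-affected 5. With the femoral arrays fitted alone 4 probe sets were called and none of the 10 named genes. FAU, CES1, FAM46C and KNG1 kept their calls without any 1 array. NUP50 lost its call without femur non-affected 3, femur non-affected 4 or femur affected 3 (adjusted p up to 0.0584), and IGFBP6 without femur affected 2, femur affected 3 or femur non-affected 4 (up to 0.0663). SREK1IP1 lost it without femur non-affected 3, femur non-affected 4, femur affected 2 or femur affected 3 (up to 0.0853), and BPIFA2 without any of these or femur affected 4 (up to 0.131). EGLN1 and RB1CC1 lost theirs without the same 4 arrays as SREK1IP1 (up to 0.139 and 0.154). Both also lost it without humerus non-affected 1, humerus non-affected 4, humerus non-affected 6, humerus affected 3 or humerus affected 4, EGLN1 without femur non-affected 1, and RB1CC1 without femur non-affected 2, humerus affected 2 or humerus affected 7. Of simulated changes in this comparison 69.9% were recovered at 1 log2 unit and 15.5% at 0.5, over 16799 genes.

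Among the lists in the femur, oxidative phosphorylation had a median of -0.23, with 24 of 25 genes negative (adjusted p = 0.00184; adjusted p = 0.890 with an estimated correlation). The myeloid genes had a median of -1.94, with 8 of 8 negative (adjusted p = 0.00526; adjusted p = 0.890 with an estimated correlation). None of them was called over all genes, and 7 of 8 were adjusted over the list alone. Among these were the complement gene C1QC at -2.79 and the receptor subunit FCER1G at -2.01. For FCER1G 1 of 8 femoral samples lay at the floor, so its difference is not exact. Cell cycle genes had a median of 0.26 (adjusted p = 0.00852; adjusted p = 0.890 with an estimated correlation), hypoxia genes 0.35 (adjusted p = 0.0220; adjusted p = 0.890 with an estimated correlation) and cartilage matrix genes 0.12, with 10 of 11 positive (adjusted p = 0.0368; adjusted p = 0.890 with an estimated correlation). The cartilage list was not called without the filter (adjusted p = 0.0958), the cell cycle list was not called with the bone list as a covariate (median 0.15, adjusted p = 0.229), and with the myeloid list as a covariate the hypoxia, oxidative phosphorylation and cartilage lists were not called, with a median of -0.05 for hypoxia. In the cartilage list the collagen COL11A1 and the link protein HAPLN1, at 1.07, passed adjusted over the list alone, and 0 did over all genes. Elsewhere the stromelysin MMP3 passed adjusted over the list alone at -3.10, the osteoblast factor DLX5 at -0.97 and CYCS at 0.74, again with 0 over all genes.

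Whether the effect of status differs between the joints was tested directly. It did for FAU, for HAAO, an enzyme of tryptophan breakdown, for AZGP1, a secreted lipid-mobilising protein, for TNFSF13, a cytokine of B cells, and for LOC396794. In each of these the affected mean was lower than the non-affected in the femur, and in the humerus it was higher except for LOC396794. Most of the interaction therefore repeats the femoral result, and 43 of its 45 probe sets were among the 192. Over all tested probe sets the differences in both joints were negatively related. The result for FAU rests on 1 of its 3 tested probe sets, since the others did not share its large femoral difference.

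FAU differed between the joints by -3.07 (adjusted p = 0.00118), HAAO by -1.62 (adjusted p = 0.00181), AZGP1 by -2.20 (adjusted p = 0.0102), TNFSF13 by -2.37 (adjusted p = 0.0135) and LOC396794 by -1.49 (adjusted p = 0.0195). HAAO averaged 6.69 in non-affected and 5.35 in affected femur. TNFSF13 and LOC396794 lost their calls with the myeloid list as a covariate (adjusted p = 0.164 and 0.104; over the alternatives other than leaving out an array they ranged from 6.55e-04 to 0.164 and from 0.00485 to 0.104). Of the 10 femoral genes, KNG1 (0.98), NUP50 (1.17), CES1 (-3.20), FAM46C (-2.71) and IGFBP6 (-2.70) were also called here. limma called 45 probe sets, 7 higher and 38 lower, with 3177 at an unadjusted p under 0.05. Across the 16799 probe sets, the femoral and humeral differences had r = -0.296, over probe sets, which are not independent replicates. Of the 192 femoral calls, 76 had the same sign in the humerus and 116 the opposite.

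The count of 45 was 21 with array weights, 220 with 23 arrays, 549 with the bone list and 6 with the myeloid list as a covariate, and 20 without both arrays of femur non-affected 1 and 2. It was moved by leaving out single arrays as well. Without femur affected 1 it was 98, without femur affected 2 22, without femur affected 3 15, without femur affected 4 77 and without femur non-affected 3 15. Without humerus non-affected 1 to 6 in turn it was 25, 70, 29, 16, 24 and 17. Without humerus affected 1, 2 or 4 it was 27, 20 and 18. Simulated changes of 1 log2 unit were recovered in 46.3% of cases and changes of 2 in 89.4%, over 16799 genes. Camera's preset called 6 lists, none with an estimated correlation. The oxidative phosphorylation genes differed between the joints by a median of -0.36 (adjusted p = 7.85e-06; adjusted p = 0.610 with an estimated correlation), and fry called them as well (adjusted p = 0.0412). The cholesterol genes differed by 1.08 and the myeloid genes by -2.81 (both adjusted p = 3.55e-04; both adjusted p = 0.610 with an estimated correlation). For hypoxia the median was 0.71 (adjusted p = 0.00120; adjusted p = 0.610 with an estimated correlation), for cartilage matrix 0.46 (adjusted p = 0.00202; adjusted p = 0.610 with an estimated correlation) and for the interferon response -1.05 (adjusted p = 0.00490; adjusted p = 0.610 with an estimated correlation). With the myeloid list as a covariate the cholesterol, hypoxia and interferon lists were not called, with medians of 0.64, 0.12 and 0.20. No list member was called over all genes, and adjusted over the list alone 7 myeloid genes, 3 oxidative phosphorylation genes, 1 interferon gene and MMP3 passed.

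Femur and humerus were then compared. BioB, a control transcript added at hybridisation, read at least 9.74 on femoral arrays and at most 8.57 on humeral ones. A difference between array runs and one between joints therefore cannot be told apart for the calls below. Femoral samples read higher for SAL1, a lipocalin of pig saliva, for CHI3L1, a glycoprotein that chondrocytes secrete, and for the chondrocyte factor SOX9. Among the genes with the largest differences, humeral samples read far higher for IBSP, COL10A1 of hypertrophic cartilage and the mineralising phosphatase ALPL. The osteoclast phosphatase ACP5, the neutrophil peptide NPG4 and a probe set of the neutrophil peptide PR39 were far higher there too. The mineralization and bone matrix lists had called members on both sides, and fry called both while camera's preset did not. Of the endothelial genes 6 of 8 and of the myeloid genes 7 of 8 were lower in the femur, again with a call by fry and none by camera's preset. Unlike camera, fry does not compare a list with the other genes, so a shift of all probe sets enters its calls. The myeloid list averaged 5.32 in affected and 7.09 in non-affected femur, against 8.37 and 7.61 in the humerus. Its site difference thus lay mostly between the affected samples. Of the skeletal muscle genes 6 of 8 were higher in the femur.

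IBSP averaged 7.63 in affected and 5.52 in non-affected femur, against 12.71 and 11.62 in the humerus, a difference of -5.57 ± 0.88 (SE, adjusted p = 4.21e-05), and all 8 femoral samples lay under the humeral mean. ACP5 differed by -5.18, NPG4 by -4.70, COL10A1 by -4.39 (adjusted p = 0.00631), ALPL by -4.19 and PR39 by -4.05. Of the 8 femoral samples 4 lay at the floor for COL10A1, 3 for IBSP, 2 for PR39 and 1 each for ALPL and NPG4. Of 13 humeral samples 2 lay there for TNNC2 and 1 for COL10A1. The floor cuts these values, so the fitted differences of these genes are not exact and have no order among them. The PR39 value is from another probe set than its status difference. At that other probe set 1 of 8 femoral and 4 of 13 humeral samples lay at the floor, and its site difference is not given here. Also lower were the fatty acid carrier FABP4 at -3.59, the granule proteoglycan SRGN at -3.22, the secreted glycoprotein MYOC at -3.22, GJA5 of arterial endothelium at -3.21 and the lipoprotein APOA1 at -3.19. PRTN3, a neutrophil protease, differed by -3.80 (adjusted p = 0.0339). It lost its call without any of femur affected 1 to 4 or without humerus affected 8 (adjusted p from 0.0521 to 0.0618). Higher in the femur were SAL1 at 4.19 (adjusted p = 6.71e-05), CHI3L1 at 2.94 (adjusted p = 1.01e-04), the fructose transporter SLC2A5 at 2.05, the peptidase CPN1 at 1.87 and angiotensinogen, AGT, at 1.84. Further up were FAU at 1.76, COL5A1 at 1.74 (0.55 to 0.89 at its other probe sets) and INTS3 at 1.65. The transcriptional coactivator CITED1 was up at 1.63, and the muscle genes MYLPF and TNNC2 at 2.45 and 2.03. For FAU only non-affected femur stood high, at 8.54, against 5.65 in affected femur and 5.37 and 5.20 in the humeral groups. Its 1.76 is thus an average over unlike femoral groups and not a trait of the femur. It also comes from 1 of 3 tested probe sets of FAU. With the bone list as a covariate SAL1, GJA5, FAU, COL5A1 and INTS3 kept their calls and the others of this paragraph lost theirs, but with different outcomes. MYLPF stayed at 2.16 and TNNC2 at 1.90, while CHI3L1 went to 1.28, CITED1 to 0.74, CPN1 to 0.56, AGT to 0.54 and SLC2A5 to 0.35. ACP5 went to -1.97, FABP4 to -1.37, IBSP, a member of that list, to -1.32, APOA1 to -1.17, SRGN to -1.03, PR39 to -0.96, MYOC to -0.72 and NPG4 to -0.58, and PRTN3 turned to 0.43. In non-affected groups alone SOX9 (0.64, adjusted p = 0.113), NPG4, PR39, PRTN3, FABP4, SRGN, APOA1, SLC2A5, AGT, MYLPF and TNNC2 were not called, and with the myeloid list as a covariate COL10A1, ALPL, PR39, PRTN3, FABP4, APOA1, SLC2A5, MYLPF and TNNC2 were not.

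**Figure D3:**
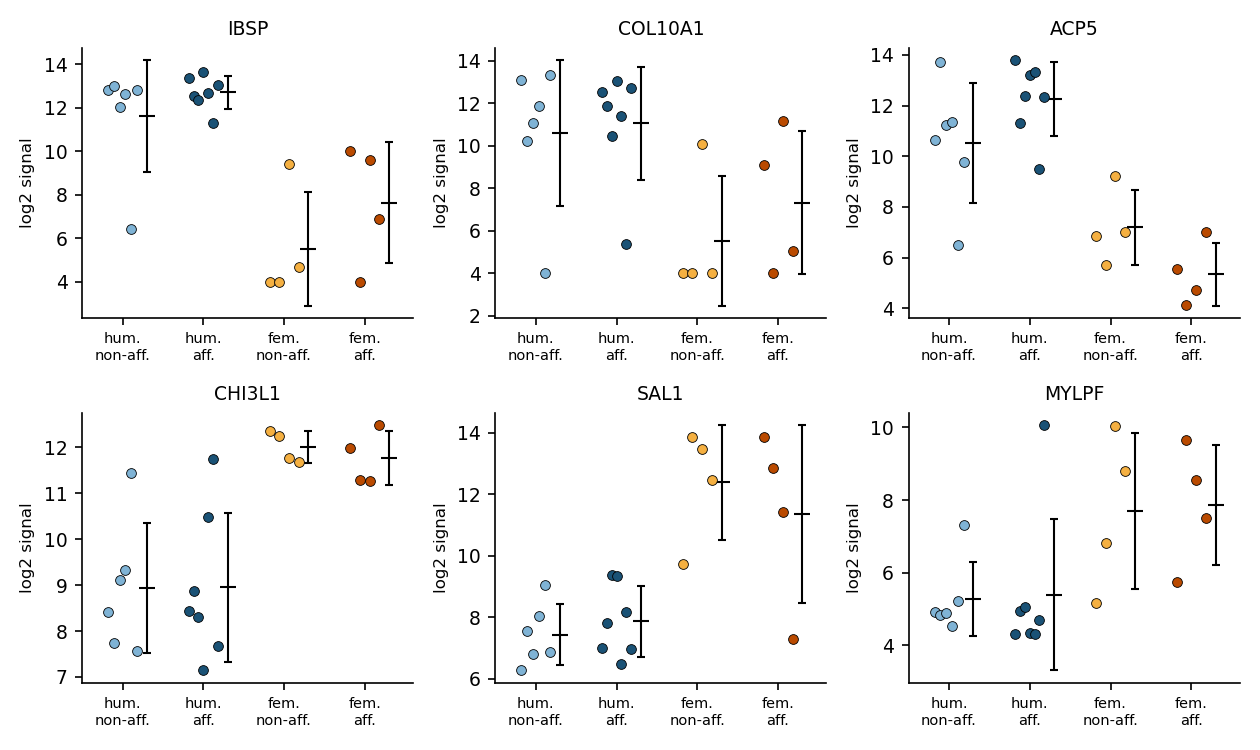
Log2 signal (vertical axis) of 6 genes called between femur and humerus, in each of the 21 samples by group (horizontal axis); the line beside each group is the mean with its SD. IBSP averages 12.71 and 11.62 in the humeral groups and 7.63 and 5.52 in the femoral ones.

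limma called 8707 of 16799 probe sets between the sites, with 9731 at an unadjusted p under 0.05. As deposited, 2963 (34.0%) were higher and 5744 lower in the femur. That balance depends on the scaling, since the median of all probe sets was -0.12 as deposited. It was 0.03 after quantile normalization, where 8636 were called and 54.9% of them higher, and 0.05 with each array centred on its median, where 8670 were called and 56.6% higher. Differences near -0.12 therefore say nothing about direction. The signal of ef1a at its 3' end exceeded that at its 5' end by 0.51 on femoral and 0.19 on humeral arrays, and whether RNA quality accounts for site calls was not tested. Simulated changes of 1 log2 unit were recovered in 91.6% of cases, over 16799 genes. Of the 94 named genes called here, 27 kept their call in every alternative; 3093 probe sets were called with 1 probe set per gene and 5043 with the bone list as a covariate, where 4296 of the 8707 calls remained, and COL10A1 and ALPL, now at 1.03 and 0.73, were not called.

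Within the lists, the mineralization genes had 3 called higher and 8 lower (median -0.89), with MMP13 at -1.43 and the parathyroid hormone receptor PTH1R at -2.01. Bone matrix had 1 higher and 3 lower (-0.23), and SP7 had 0.80 and -0.02 at its probe sets. Of the osteoclast genes 1 was higher, the calcitonin receptor CALCR at 0.68, and 5 were lower (-1.32), with the integrin ITGB3 at -3.10. Endothelial genes had 1 higher, ESAM at 0.48, and 6 lower (-2.19), with the cadherin CDH5 at -2.92 and the claudin CLDN5 at -2.58. In smooth muscle 2 were lower (-0.45), CNN1 at -3.08 and ACTA2 at -2.86. Of the myeloid genes 7 of 8 were lower (-1.96), such as AIF1 at -2.49 and TYROBP at -2.31, and of the neutrophil genes 6 of 6 (-2.61), such as LTF at -2.99. The globin HBB was 1 of 4 erythroid genes called, at -0.88, and JCHAIN 1 of 2 lymphocyte genes, at -2.08. Synovial and fibrous genes had 1 higher and 7 lower (-0.84), with MFAP5 at -2.32. The adipocyte list had 2 higher, LEP at 0.80 and ADIPOQ at 0.48, and 3 lower over all genes or 4 adjusted over the list alone; its median was -1.30 while camera's direction was up. Adjusted over the list alone the counts of the other lists of this paragraph were the same. The erythroid and lymphocyte lists were too short to test as lists, and none of the others passed camera's preset in the site comparison; after quantile normalization the myeloid list did (adjusted p = 0.0422), and the bone median was -0.11. By fry all of those tested except the adipocyte list were called lower, with adjusted p from 6.47e-04 to 0.0136. However, fry tests a list against no change and not against the other genes, and 8707 of 16799 probe sets were called. It was run only on the values as deposited, where the median of all probe sets was -0.12. Its calls therefore do not show that a list differs from the other genes, nor that its direction is free of the scaling. Femoral samples at the floor numbered 5 of 8 for LTF, 4 for MFAP5, 3 for ITGB3 and 2 each for AIF1 and JCHAIN. CDH5, CNN1 and TYROBP had 1 each. The fitted differences of these genes are therefore not exact. With the bone list as a covariate MMP13, PTH1R, CALCR, ITGB3, CDH5, CLDN5, CNN1, ACTA2, AIF1, TYROBP, LTF, JCHAIN and MFAP5 lost their calls. In non-affected groups alone CDH5, AIF1, TYROBP, LTF and JCHAIN did, and with the myeloid list as a covariate, which holds AIF1 and TYROBP, the last 4 of these.

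The 41 cytosolic ribosomal protein genes had 35 lower and 0 higher (36 and 1 adjusted over the list alone) and a median of -0.28 (adjusted p = 6.68e-07; adjusted p = 0.828 with an estimated correlation). After quantile normalization that median was 0.00 and the adjusted p 0.994, so their direction rests on the scaling. RPL23 had probe sets of both signs, -0.43 and 1.11. Of 25 oxidative phosphorylation genes 17 were lower (17 adjusted over the list alone; median -0.29, -0.17 after quantile normalization), such as NDUFB3 at -0.92 (adjusted p = 0.0107; adjusted p = 0.828 with an estimated correlation). Of 17 cell cycle genes 13 were lower (13 adjusted over the list alone; median -0.94, -0.78 after quantile normalization), such as PCNA at -1.07 and CCNB2 at -1.04, with 1 of 8 femoral samples at the floor (adjusted p = 0.0107; adjusted p = 0.828 with an estimated correlation). Of 15 hypoxia genes 7 were higher (7 adjusted over the list alone; median 0.51, 0.66 after quantile normalization), such as the demethylase KDM3A at 0.87 (adjusted p = 0.0107; adjusted p = 0.828 with an estimated correlation). Probe sets of VEGFA differed, with 1.54 and -0.32 among them. Of 8 skeletal muscle genes 6 were higher (6 adjusted over the list alone; median 1.27, 1.42 after quantile normalization), such as TNNT3 at 0.64 (adjusted p = 0.0107; adjusted p = 0.828 with an estimated correlation); after quantile normalization the adjusted p was 0.0741. KDM3A and CCNB2 lost their calls with the bone list as a covariate, VEGFA also with the myeloid list and in non-affected groups alone, and TNNT3 with the muscle list, which holds it. With the bone list as a covariate the hypoxia median turned to -0.14, the cell cycle median was -0.25 and that of oxidative phosphorylation -0.14 (each adjusted p = 0.997), while the muscle median stayed at 1.36 with an adjusted p of 0.0510. With the myeloid list as a covariate hypoxia was at 0.12 and oxidative phosphorylation at -0.15 (both adjusted p = 0.700).

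The remaining lists were not called between the sites by camera's preset, while fry called matrix proteases (adjusted p = 0.00265), inflammation (adjusted p = 0.0425), apoptosis (adjusted p = 7.75e-04) and Wnt signalling (adjusted p = 0.00182) lower. Cartilage matrix genes split, with SOX9 at 1.15 and LUM, a keratan sulfate proteoglycan, at -2.96; 2 were higher and 3 lower (the same adjusted over the list alone), and the median of -0.01 and mean of -0.19 differ in sign from camera's direction and from the median of 0.29 after quantile normalization. Matrix proteases had 0 higher and 9 lower (-0.87), with the aggrecanase-family ADAMTS1 and cathepsin CTSS lower at each of their probe sets given, -2.58 and -2.49, and -1.89 and -3.11. Inhibitors of proteases had 1 higher and 3 lower, with a median of -0.14 that was 0.02 after quantile normalization. Inflammation genes had 1 higher and 8 lower (7 adjusted over the list alone; -0.56), with the receptor TLR4 at -1.67, and interferon genes 1 and 7 (-0.49, or -0.30 after quantile normalization). The unfolded protein response had 4 and 4 (3 and 4 adjusted over the list alone; 0.14, or 0.26 after quantile normalization), apoptosis 1 and 2 (-0.14, or 0.01 after quantile normalization), TGF-beta and BMP signalling 2 and 4 (0.00, or 0.17 after quantile normalization) and Wnt signalling 1 and 3 (1 and 7 adjusted over the list alone; -0.35, or -0.18 after quantile normalization). Cholesterol synthesis had 1 lower (0 adjusted over the list alone; -0.40) and the immediate early genes 1 and 5 (-0.23, or -0.08 after quantile normalization), with FOS at -0.89. Counts of this paragraph with no second value were the same adjusted over the list alone. The fry calls of this paragraph have the limit given above for fry. In the limb identity list MEIS2 at 1.40 and MEIS1 at 0.74 were higher, and the median was 0.28 (0.42 after quantile normalization). Both lost their calls in non-affected groups alone (adjusted p = 0.0576 and 0.172), where SOX9, LUM and TLR4 did too, and with the bone or the myeloid list as a covariate. LUM lost its call with either covariate as well, and TLR4, FOS, ADAMTS1 and CTSS with the bone list. In the same list HOXA9 was lower at -0.41, a call lost under both scalings, in non-affected groups alone, with 23 arrays, with the muscle list as a covariate and without any of femur affected 1, 2 or 3, femur non-affected 3, 4 or 5, humerus non-affected 1, 3 or 4, or humerus affected 7 or 8 (adjusted p from 0.0554 to 0.0850); PITX1, TBX4 and TBX5, which separate fore and hind limb, have no named probe set.

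**Figure D4:**
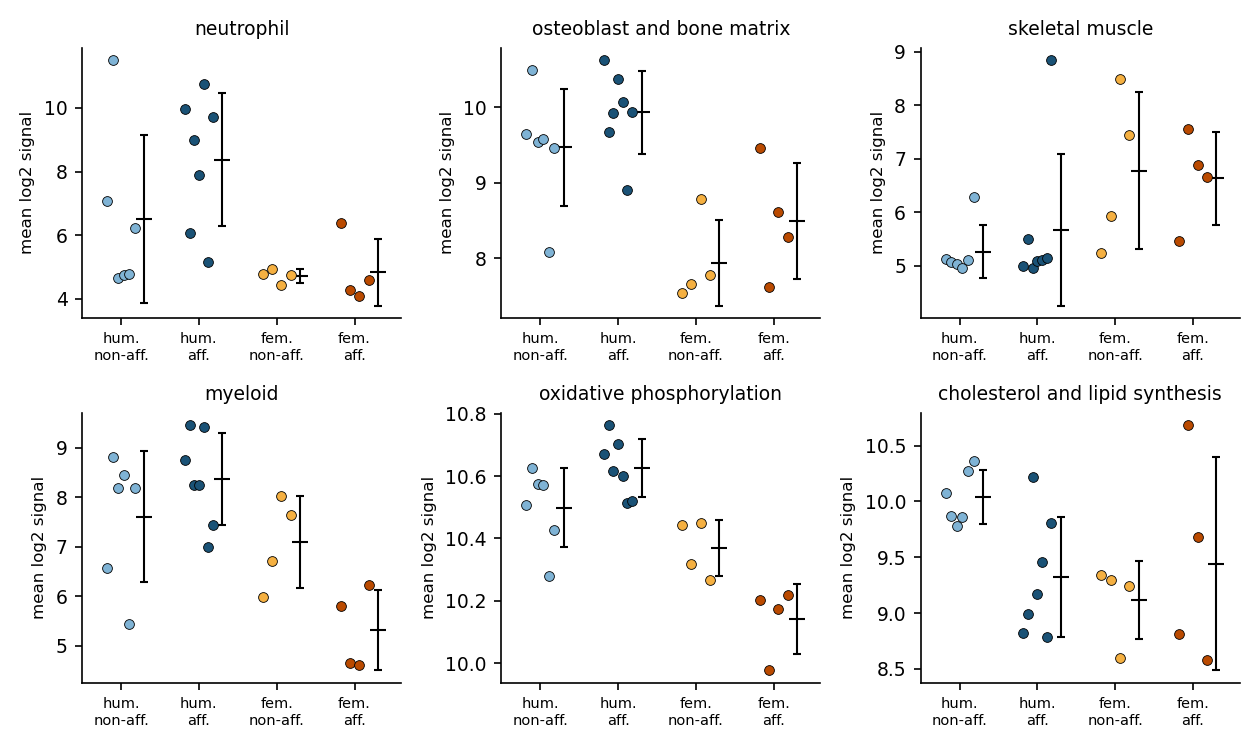
Mean log2 signal of the members of 6 lists (vertical axis) in each of the 21 samples by group (horizontal axis); the line beside each group is the mean with its SD. The neutrophil list reaches 11.50 in humerus non-affected 2, and the skeletal muscle list reaches 8.84 in humerus affected 8 while most humeral samples stay near 5.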

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

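The myeloid and bone covariate tests, the reading of the control transcripts as separate runs and the correlation of neutrophil with erythroid genes were chosen only after the results were seen. Of 644 groups of samples checked for 1 sample far from the others, 72 had such a sample, where chance gives about 1 in 20. They cluster in a few samples, and all values here are log2 signals.

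Humerus non-affected 5 lay apart most often. It was the lowest of its group for IBSP (6.41), COL10A1 (4.01), ALPL (4.64), APOA1 (6.90), FAM46C (5.67), TNFSF13 (5.82), PCNA (7.79) and the hypertrophy and mineralization list (8.03). It was the highest for CPN1 (10.01), AGT (10.96), P4HA2 (12.93), MEIS1 (7.67), MEIS2 (8.64), the hypoxia list (11.37) and the unfolded protein response list (10.36). Whether its site label is right was not tested. Its BioB signal of 8.57 lies with the humeral arrays. Without it the interaction called 24 probe sets, the humerus 0 and the site comparison 8886.

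Femur non-affected 4 showed the reverse, being the highest of its group for IBSP (9.42), COL10A1 (10.11), ALPL (9.98), MYOC (8.47), CNN1 (5.65) and the hypertrophy and mineralization list (9.09), and the lowest for the cholesterol list (8.60). Humerus affected 7 was the lowest for COL10A1 (5.38), ALPL (7.97), APOA1 (8.75), MMP13 (5.10) and the hypertrophy list (8.44), and the highest for the limb identity list (8.77). Muscle genes stood out in humerus affected 8, with the muscle list at 8.84, MYLPF at 10.07, TNNC2 at 9.66, MYL1 at 9.67, CKM at 10.31, MYH7 at 7.87 and TNNT3 at 6.34. They did so to a lesser degree in humerus non-affected 6, with the list at 6.28, MYLPF at 7.31, TNNC2 at 6.77, MYL1 at 7.18 and CKM at 6.51. Humerus non-affected 2 was the highest for the neutrophil list (11.50), PRTN3 (17.50), S100A12 (9.29), AHSP (8.93), SP7 (8.03) and CALCR (8.13). Femur affected 1 was the highest for the erythroid list (7.85), NPG4 (11.02), LTF (7.10), PR39 (7.26), AHSP (6.76) and MEIS2 (8.73). The PR39 values of this section are from another probe set than its site difference.

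Other single samples lay apart without such company. Femur affected 2 was the lowest for the cartilage matrix list (11.70), MYOC (4.48) and NUP50 (6.90). Femur affected 4 was the lowest for the immediate early list (9.97) and the highest for the adipocyte list (6.71), CES1 (5.07), GJA5 (5.37) and CDH5 (7.14), and femur affected 3 the lowest for PRTN3 (7.04) and the highest for ADIPOQ (5.96) and COL11A1 (11.53). In non-affected femur, sample 1 was the lowest for APOA1 (4.86) and MMP13 (4.06), and sample 3 the lowest for PR39 (4.002) and MMP3 (4.84) and the highest for ACAN (13.67). In the humerus, affected 2 was the highest for SLC5A1 (7.23) and the lowest for CILP (8.96), affected 1 the lowest for HBB (6.26), and non-affected 1 the highest for PR39 (7.05).

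The effect of status differed between the joints, by the interaction test, for FAU (-3.07), CES1 (-3.20), FAM46C (-2.71), IGFBP6 (-2.70), TNFSF13 (-2.37), AZGP1 (-2.20), HAAO (-1.62), LOC396794 (-1.49), KNG1 (0.98) and NUP50 (1.17). For FAU, FAM46C and KNG1 the other probe sets of the gene did not share the size of the femoral difference. Lists that differed by camera's preset were the myeloid (-2.81), interferon (-1.05) and oxidative phosphorylation (-0.36) lists, and those for cartilage matrix (0.46), hypoxia (0.71) and cholesterol (1.08), all at an adjusted p of 0.610 with an estimated correlation. Of 100 splits of the samples by status within each site, 2 gave 45 or more probe sets, the real one included. The other gave 390, several times the real count, so the samples have a structure besides status. That share lies under the bound fixed beforehand. However, 43 of the 45 probe sets were among the femoral calls, for which chance is not excluded. Neither chance nor that structure is therefore excluded here.

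Every non-affected femoral sample lay outside the range of the other 17 samples in 63 of the 192 femoral calls, and every affected one in 36, while the affected mean lay nearer the humerus in 54.7% of the calls against 50.4% of all probe sets, so the non-affected samples stood apart in a minority of calls only, with status as the biological explanation that stays open. Of the 35 splits of the 8 femoral samples, 2 gave 192 or more, the real one included, and the other gave 323, so chance is not excluded. Macrophage-like cells in unequal shares would shrink the differences once the myeloid list is a covariate, but their median ratio was 0.938 (quartiles 0.831 to 1.06). The median size went from 0.86 to 0.81 and the median SE from 0.18 to 0.21, so that 62 of the 192 calls remained. Signals carried by 1 probe set of a gene may explain part of the calls. Over 41 genes the other probe sets showed a median of 0.392 of the called difference (quartiles 0.100 to 0.692). In 3 of these genes a second probe set was called, and in 34 all probe sets had 1 sign. Over all 1615 genes with several probe sets the median ratio was 0.555. There the reference probe set was drawn at random and not by its smallest p, so both ratios are not alike. This explanation stays open.

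Control transcripts added at hybridisation differed by site, with BioB 1.55 and BioC 1.54 higher on femoral arrays, in data that no comparison uses. The brighter controls differed less, with BioD at 12.85 on femoral and 12.09 on humeral arrays, and Cre at 13.93 and 13.64. The dap, lys, phe and thr controls averaged 9.16 and 9.20. Whether brighter femoral hybridisation causes site calls stays open, because arrays of similar medians fix the shift of the 1266 probe sets as bright as BioB, a median of -0.14 and a ratio of -0.0910 to the shift of BioB. Bone in the humeral pieces, as far as the bone list measures it, is not the whole cause. With that covariate the median ratio of the differences was 0.925 (quartiles 0.579 to 1.24), and 4296 of the 8707 calls remained. The neutrophil median went from -2.61 to 0.18, the osteoclast median from -1.32 to 0.09 and the hypoxia median from 0.51 to -0.14. The skeletal muscle median stayed, at 1.36. The ribosomal median was -0.32, but without the covariate it was 0.00 after quantile normalization. It therefore rests on the scaling and does not bear on bone. The covariate was run only on the values as deposited. The lowest femoral BioB (9.74) exceeded the highest humeral one (8.57) by 1.17, so a probe-by-probe difference between runs and a difference between joints cannot be told apart for the site calls. Of 100 splits of the samples, 1 gave as many as 8707 probe sets, the real one, and the highest other gave 3654. A chance split is thus unlikely to give such a count, but these splits cannot show a share under 1 in 100. They also treat the samples as separate animals, which the labels do not state.

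Neutrophil granule genes varied over the humeral samples more than between the groups. The test of the list mean between 7 affected and 6 non-affected samples gave a two-sided exact permutation p of 0.177, so a chance difference stays open. Blood-forming marrow in some pieces may explain it, because the list rose with the erythroid list over 13 samples (r = 0.846, permutation p = 5.3e-04; rho = 0.835). The relation held without the 2 farthest samples (r = 0.714) and within 6 non-affected and 7 affected samples (r = 0.923 and 0.782), and its adjusted p was 0.00216 over 12 relations. It rose about as closely with osteoclast genes (r = 0.838, adjusted p = 0.00216), which leaves bone tissue open beside marrow.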

How the results depend on the processing

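The 23 arrays as separate samples, the fits without a close pair and the covariates were tests chosen only after the results were seen. No paired analysis was possible because the labels do not say which samples are sibs. An offset before the logarithm was not run, since the values are already log2.

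The counts for status over both sites (0), the humerus (0), the femur (192), the interaction (45) and the sites (8707) stayed within 1.5 times the value under no filter, a stricter filter, quantile normalization, median centring, a raised floor and a trended, robust prior. Array weights gave 59 in the femur and 21 for the interaction. With 1 probe set per gene, where fewer are tested, the femur gave 67 and the sites 3093. The equal-weight mean of the within-site differences gave 22 over both sites, and femoral arrays alone, with fewer samples, gave 4. With 23 arrays the femur gave 600 and the interaction 220. The bone covariate gave 1577, 549 and 5043 for the femur, the interaction and the sites, and the myeloid covariate 87 and 6 for the femur and the interaction. Without both arrays of femur non-affected 1 and 2 the interaction gave 20. Leaving out 1 array at a time gave 53 to 450 in the femur, 15 to 98 for the interaction and 8111 to 9023 for the sites. Apart from fewer genes or samples, the cause was not tested.

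Of the 26 lists, camera's preset called 3, 11, 5, 6 and 5 in these comparisons, in the order above. The estimated correlation called 0 of the 26 in each comparison, and fry called 0, 0, 0, 1 and 15 of them. The bone covariate called 0 lists over both sites, 6 in the humerus and 1 between the sites; the myeloid covariate called 9, 6 and 3. The cause was not tested.

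Of the 94 named site genes called, 27 kept the call in every alternative and 67 lost it in some; all 10 femoral genes lost it in some. Signs reversed as follows, and the cause was not tested. With the bone covariate the site difference was 1.03 for COL10A1, 0.73 for ALPL, 0.43 for PRTN3, 1.30 for BGLAP, which that list holds, 0.72 for AHSP, 0.85 for HBM, 0.16 for LTF and 0.0691 for S100A8. The status difference was then -0.0137 for CTSD, 0.0644 for P4HA2, -0.35 for BGLAP, -0.0026 for TIE1, -0.0503 for AHSP, -0.0284 for ALAS2 and -0.0339 for FABP4. MYL1, a muscle gene called higher in the femur, was at -0.10 between the sites with the muscle covariate, which holds it. Its adjusted p reached 0.746 over the alternatives other than leaving out an array, and 0.113 without 1 array. CD8A, near 0 between the sites, was at 0.10 after quantile normalization, 0.14 after median centring, 0.11 with array weights, 0.15 in non-affected groups, 0.0118 with 23 arrays, 0.0464 with the bone covariate and 0.0473 with the muscle covariate. JCHAIN, near 0 for status, was at 0.10 with 23 arrays or the myeloid covariate. Leaving out 1 array gave -0.130 to 0.0597 for CD8A, -0.339 to 0.237 for JCHAIN, -0.0429 to 0.688 for CKM and -0.0575 to 0.341 for MYH7, the last 2 for status and lowest without humerus affected 8.

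Signal near the floor limits what the arrays show: on average 4.55% of the probe sets of a femoral array lay there.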

Other observations

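The myeloid covariate and the correlations between lists were tests chosen only after the results were seen. Skeletal muscle genes varied between femoral samples: the list averaged 8.50 in femur non-affected 4, 7.55 in femur affected 2 and 7.44 in femur non-affected 5, but 5.24 in femur non-affected 1 and 5.46 in femur affected 1. PRTN3 was either near 7 or very high. It read 17.50 in humerus non-affected 2, 16.95 in humerus affected 5, 16.40 in humerus affected 1, 15.83 in humerus affected 8, 14.32 in humerus affected 3 and 14.03 in humerus affected 4, and at most 7.53 in the other 15 samples.

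Over the 13 humeral samples the myeloid list rose with the oxidative phosphorylation list (r = 0.810, permutation p = 9.8e-04; rho = 0.808) and with the interferon list (r = 0.841, permutation p = 2.7e-04; rho = 0.709), and fell with the hypoxia list (r = -0.696, permutation p = 0.00808; rho = -0.654). Their adjusted p over 12 relations were 0.00257, 0.00216 and 0.0162. Between 4 affected and 4 non-affected femoral samples the mean of the oxidative phosphorylation list differed by -0.23 (two-sided exact permutation p = 0.0286, the smallest that 4 against 4 allows) and that of the myeloid list by -1.78 (exact permutation p = 0.0571), and neither passed adjustment over 56 tests. With the myeloid list as a covariate, the oxidative phosphorylation genes in the femur had a median of -0.13 and an adjusted p of 0.163 by camera's preset. Over the alternatives that adjusted p ran from 6.38e-05 to 0.890.

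Status over both sites gave 1223 probe sets at an unadjusted p under 0.05, where 839.95 would fall by chance on independent genes. Of 100 splits of the samples by status within each site 9 gave as many, and the highest other gave 1804, so chance is not excluded. In the humerus 21 of 100 splits gave 1100 or more, and the highest other gave 3052, so chance is not excluded there either.

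The arrays of both joints also differed in control values. The ef1a control read 0.51 higher at its 3' than at its 5' end on femoral arrays (0.27 to 0.84) and 0.19 higher on humeral ones (0.14 to 0.28), on average. Run, RNA quality and site were not separated by any test here, so this bears on the site calls too. Within the femur the ef1a gap averaged 0.59 on affected arrays (0.27 to 0.84) and 0.45 on non-affected ones (0.32 to 0.71). Its part in the femoral and interaction calls was not tested.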
